A study of Mus musculus with 4 samples.

How the data were processed

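The series holds 10x 3' single-cell libraries of CD45-enriched hepatic non-parenchymal cells, 2 from sedentary and 2 from exercised mice. The deposited matrix holds UMI counts per gene and cell barcode, which the authors made with the Cell Ranger aggregation. Per the submitters' processing notes the version was 7.0.0 with builds mm10 and GRCm38, while the header of the matrix gives 6.1.1. Whether the aggregation equalised read depth between libraries was not stated. The matrix has 31053 genes and 51140 columns, of which 28525 carry a barcode with 135480097 UMIs. The other 22615 columns were not used here. The number after each barcode was read as the order of the libraries in the aggregation table, which is a limit of every comparison. The ends of the 4 barcode blocks were checked against changes in the matrix columns, and the breaks lay 6, 2 and 33 cells from them. The Kupffer-like sums held from 495687 to 6040053 UMIs per library.

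Cells with at least 200 genes and at most 10% mitochondrial UMIs were kept (500 genes and 5% in the stricter filter). Doublets were scored per library with the Scrublet of scanpy 1.11.5. Its automatic thresholds marked 3.94%, 4.84%, 0.17% and 0.14% of the cells, so the highest scores up to the expected rate of 0.8% per 1000 cells were removed instead, 422, 462, 293 and 144 cells. The UMIs were scaled to 10000 per cell and logged, and 2000 variable genes, 30 principal components and 15 neighbours went into Leiden clustering (leidenalg 0.10.2) at resolution 1, with T, NK and dendritic cells clustered again on 20 components. A cluster took the class whose marker list had the highest score if that was at least 1.0 and 3 markers were detected in 10% of its cells, unless its 10 leading genes held more markers of another class. Classes carry the ending -like, since they rest on markers alone. Other Python packages were anndata 0.12.19, scikit-learn 1.9.0, scipy 1.17.1, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, under Python 3.11.15.

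UMIs were summed per library and class, and classes with at least 30 cells in every library were tested. Genes were tested with the quasi-likelihood F test of edgeR 4.0.16 (robust, filterByExpr, TMM) in R 4.3.3, with the Benjamini-Hochberg adjustment and a threshold of 0.05. The DESeq2 1.42.0 Wald test was run beside it. Cells per class were tested with edgeR, with the log of all named immune cells as offset. The 33 gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 on log CPM with a prior count of 2, and with an estimated correlation and fry. The exact permutation test on 2 against 2 libraries has a smallest two-sided p of 0.333. Markers, gene lists, tests, the naming rule and the first set of alternatives were fixed before the data were examined. The rule for ribosomal proteins also took in Rps6ka kinases, and that for oxidative phosphorylation took in Sdhaf1. The rule named, among called genes with at least 10 CPM in the higher group and no overlap between the groups, the 12 largest rises and falls in Kupffer-like cells and 3 in each other class, with up to 4 members per list and a set picked in advance. A gene that this rule named is not reported here. Of the called Kupffer genes 5 were hidden from naming, being ribosomal, mitochondrial, predicted or receptor segment genes. Where a group had 0 counts the fold is a bound at a floor of 3 counts, and where it had 1 to 3 the ratio has a 95% counting interval.

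The alternatives were DESeq2 size factors, no low-count filter, the stricter cell filter, doublets kept, resolutions 0.5 and 2, a replicate block, each library left out, and sums thinned to the smallest total. Others were chosen after the data had been seen: leaving out the Kupffer-like cluster of few UMIs, leaving out genes whose level free RNA could give by the share of B cell RNA, the same with hepatocyte RNA in the share, and all kept cells as the denominator of shares. The hepatocyte version left 374 of 8387 genes, and the B cell version was made the main one after that was seen. A gene counted as one that free RNA could give if its level was at most 2 times that share times its level over all cells. Positions came from GENCODE vM21 and matched 8382 of 8387 genes. For the test on simulated data 8387 genes were drawn, of which 8121 passed the count filter and were run. Of those drawn, 24 of 100 changed 2-fold, 93 of 100 changed 4-fold and 3 of 8187 unchanged were called. The changes were planted in genes above 10 CPM, and each gene took the trended spread of the real fit.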

Results

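The data were single-cell RNA profiles of hepatic immune cells from male mice aged 8 weeks that carried MC38 tumours, a mouse colorectal cancer line, in a model of liver metastasis after surgical stress. Livers were taken 3 weeks after tumour injection, and CD45-positive cells were enriched with beads from the non-parenchymal fraction. CD45 is the surface protein shared by blood-derived cells. There were 2 groups of 2 libraries each: sedentary mice (Sed 1 and Sed 2) and mice that exercised before the operation (Ex 1 and Ex 2). The labels number the libraries and do not say that each came from a separate animal, so p-values then measure only the spread between these samples. The used part of the matrix held 37563756 UMIs in 7992 barcodes of Sed 1, 41027638 in 8224 of Sed 2, 32969739 in 7012 of Ex 1 and 23918964 in 5297 of Ex 2. After filtering and removal of called doublets, 6839, 7141, 5763 and 4097 cells remained, with median depths of 3286, 3286, 3747 and 3701 UMIs. The median mitochondrial share was higher in the kept cells of the exercised mice, at 3.92% and 4.36%, than in those of the sedentary mice, at 2.61% and 2.95%. Errors below are SD for CPM and percent and SE for log2 changes, with n = 2 libraries per group. The SE was worked back from the edgeR test, as the size of the log2 change over the square root of its F statistic. Log2 changes run from sedentary to exercised.

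The first comparison asked what exercise before surgery does to Kupffer cells, the resident macrophages of the liver sinusoids. In Kupffer-like cells of exercised mice 5 of 16 MHC class II genes tested, which present antigen to CD4 T cells, were higher than in sedentary mice: H2-Aa went from 899 ± 203 to 4140 ± 133 CPM and its invariant chain Cd74 from 2937 ± 916 to 10050 ± 406 CPM. Cxcl9, a chemokine that draws CXCR3-bearing T and NK cells, rose from 14.8 ± 7.81 to 236 ± 39.7 CPM. Cxcl9 was also a leading gene of the cluster of other macrophages. Whether such cells among the Kupffer-like ones gave its rise was not tested. In the other direction, 8 of 37 interferon-stimulated genes fell, among them Ifit3 from 274 ± 10 to 74.4 ± 11 CPM and Irf7, a transcription factor of the type I interferon response, from 1044 ± 119 to 379 ± 3.74 CPM. Ccl24, a chemokine for eosinophils, went from 777 ± 271 to 176 ± 48.6 CPM. Of 8387 genes tested, 64 rose and 41 fell in the exercised libraries (edgeR, adjusted p under 0.05), 1003 passed an unadjusted p of 0.05, and DESeq2 called 99, of which 61 were shared. All 105 called genes had both exercised libraries on one side of both sedentary ones, as did 46.4% of all genes tested, against 33.3% by chance. The cells behind these sums numbered 412, 1326, 609 and 147 in Sed 1, Sed 2, Ex 1 and Ex 2, with 1385861, 6040053, 1413018 and 495687 UMIs. The count depended on single libraries: it was 249 without Sed 1, 420 without Sed 2, 132 without Ex 1 and 61 without Ex 2, and 32 of the 61 were among the 105.

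Among the genes with the largest rise, Slpi, a secreted protease inhibitor, changed by 4.63 ± 0.36 (adjusted p = 0.000197), from 10.2 ± 2.64 to 242 ± 89.2 CPM. Cxcl9 changed by 4.13 ± 0.38 (adjusted p = 0.00133). The Fc receptor-like gene Fcrls rose by 3.75 ± 0.61, the G protein-coupled receptor gene Gpr132 by 3.41 ± 0.67, the interleukin-21 receptor gene Il21r by 3.13 ± 0.50, the phosphodiesterase gene Pde3b by 3.10 ± 0.50 and the integrin gene Itga6 by 3.00 ± 0.37, with adjusted p between 0.00323 and 0.0303. Stat4, Ablim1 and Ahnak rose by 3.69 ± 0.73, 3.57 ± 0.59 and 2.92 ± 0.36, but free RNA could give their levels in the exercised libraries. Prg4, which encodes the lubricant proteoglycan 4, had 1 UMI in the sedentary and 50 in the exercised libraries, a ratio of 194.5 with a counting interval of 33.4 to 7835. Mup20, a urinary protein made by hepatocytes, had 2 and 41 UMIs, a ratio of 79.8 (20.7 to 681). These intervals cover counting error only. With doublets kept the log2 change of Prg4 was 2.38 instead of 7.02 (adjusted p = 0.768), that of Itga6 1.90 (0.342) and that of Ablim1 1.79 (0.156). Slpi, Cxcl9, Itga6 and Ahnak stayed past the threshold without any 1 library. Without Ex 2 the adjusted p was 0.22 for Mup20, 0.0668 for Fcrls, 0.393 for Stat4, 0.203 for Ablim1, 0.574 for Gpr132 and 0.104 for Pde3b. Without Ex 1 it was 0.196 for Fcrls, 0.233 for Ablim1 and 0.285 for Il21r, and without Sed 1 0.178 for Stat4, which passed in 5 of 10 alternatives. Without Sed 2, where Sed 1 held 0 UMIs of both, the log2 changes of Fcrls and Stat4 were 7.78 and 6.51.

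The largest falls were those of Socs2, a suppressor of cytokine signalling, at -2.56 ± 0.42 (adjusted p = 0.014), the membrane repair gene Dysf at -2.34 ± 0.39, Ccdc125 at -2.28 ± 0.38, Ccl24 at -2.16 ± 0.33 (adjusted p = 0.0119) and the interferon-induced Oasl1 at -2.05 ± 0.29 (adjusted p = 0.00544). They were followed by Pde7b at -1.98 ± 0.43, Micall2 at -1.94 ± 0.41, Plac8 at -1.89 ± 0.32, Ifit3 at -1.86 ± 0.26, Id1, an inhibitor of DNA binding, at -1.86 ± 0.27, Trim30b at -1.83 ± 0.37 and the fatty acid binding protein gene Fabp7 at -1.81 ± 0.28. Ccl24 and Apoc1, which is described with the lipid genes, also led both clusters that were named Kupffer-like and Fabp7 the one of few UMIs, and Cxcl9 was a leading gene of the cluster of other macrophages. Of the 2 Kupffer-like clusters, the one of few UMIs held 59.4% of the cells pooled over the sedentary and 76.2% of those pooled over the exercised libraries. It held 300 of 412 cells in Sed 1, 732 of 1326 in Sed 2, 481 of 609 in Ex 1 and 95 of 147 in Ex 2. The shares of single libraries thus overlapped between the groups. Socs2, Dysf, Oasl1, Ifit3 and Id1 stayed past the threshold without any 1 library. Without Ex 1 the adjusted p was 0.109 for Ccdc125, 0.0665 for Ccl24, 0.0845 for Pde7b, 0.142 for Micall2, 0.0707 for Plac8 and 0.0772 for Fabp7. Without Ex 2 it was 0.135 for Pde7b, 0.115 for Micall2, 0.229 for Plac8, 0.117 for Trim30b and 0.0975 for Fabp7. Pde7b passed in 6 of 15 alternatives, Micall2 in 6 of 16 and Trim30b in 9 of 15. All of these are protein-coding genes in GRCm38 (GENCODE vM21). Slpi (ENSMUSG00000017002) lies on chromosome 2 at 164354070 to 164389095, Cxcl9 (ENSMUSG00000029417) on chromosome 5 at 92321347 to 92328079, Ccl24 (ENSMUSG00000004814) on chromosome 5 at 135569937 to 135573049, Oasl1 (ENSMUSG00000041827) on chromosome 5 at 114923240 to 114937915 and Ifit3 (ENSMUSG00000074896) on chromosome 19 at 34583531 to 34588731. H2-Ab1 (ENSMUSG00000073421), H2-Aa (ENSMUSG00000036594) and H2-Eb1 (ENSMUSG00000060586) neighbour each other on chromosome 17 at 34257689 to 34269419, 34282744 to 34287823 and 34305867 to 34316674, and Cd74 (ENSMUSG00000024610) lies on chromosome 18 at 60803848 to 60812652.

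Of the genes picked in advance for this class, the Kupffer markers did not pass the test: Clec4f had a log2 change of -1.03 ± 0.33 (adjusted p = 0.213), Vsig4 -0.52 ± 0.29, Cd163 -0.84 ± 0.57, Timd4 -0.19 ± 1.25 and Marco 0.06 ± 0.51. The same held for the cytokines Il1b at 2.27 ± 1.29, Tnf at 0.84 ± 1.75 and Il10 at -0.51 ± 1.30, and for the chemokines Cxcl10 at -0.04 ± 0.83 and Cxcl16 at 0.76 ± 0.25. Ex 2 alone held the high values of Il1b, with 1343 ± 1435 CPM over the exercised against 277 ± 72 CPM over the sedentary libraries. The metabolic genes Arg1, Acod1 and Cpt1a changed by 0.34 ± 0.29, 1.78 ± 1.45 and 0.14 ± 0.38. H2-K1, a class I gene, changed by 0.04 ± 0.26, the PD-L1 gene Cd274 by -0.27 ± 0.31, Spp1 by -0.86 ± 0.54 and Trem2 by -0.36 ± 0.34. None of these passed adjusted p 0.05, the smallest being that of Clec4f. Without Sed 1 Clec4f (-1.43, adjusted p = 6.31e-07) and Cd163 (-1.34, adjusted p = 0.0031) passed. Without Sed 2 Timd4 (1.87, adjusted p = 9.51e-05), Marco (1.00, adjusted p = 0.0345) and Spp1 (-1.36, adjusted p = 0.0141) did. Without Ex 1 Il1b (3.07, adjusted p = 0.000838) and Tnf (1.83, adjusted p = 0.0137) passed, and without Ex 2 Tnf (-2.38, adjusted p = 0.0217) and Il10 (-2.63, adjusted p = 0.0433).

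**Figure D1:**
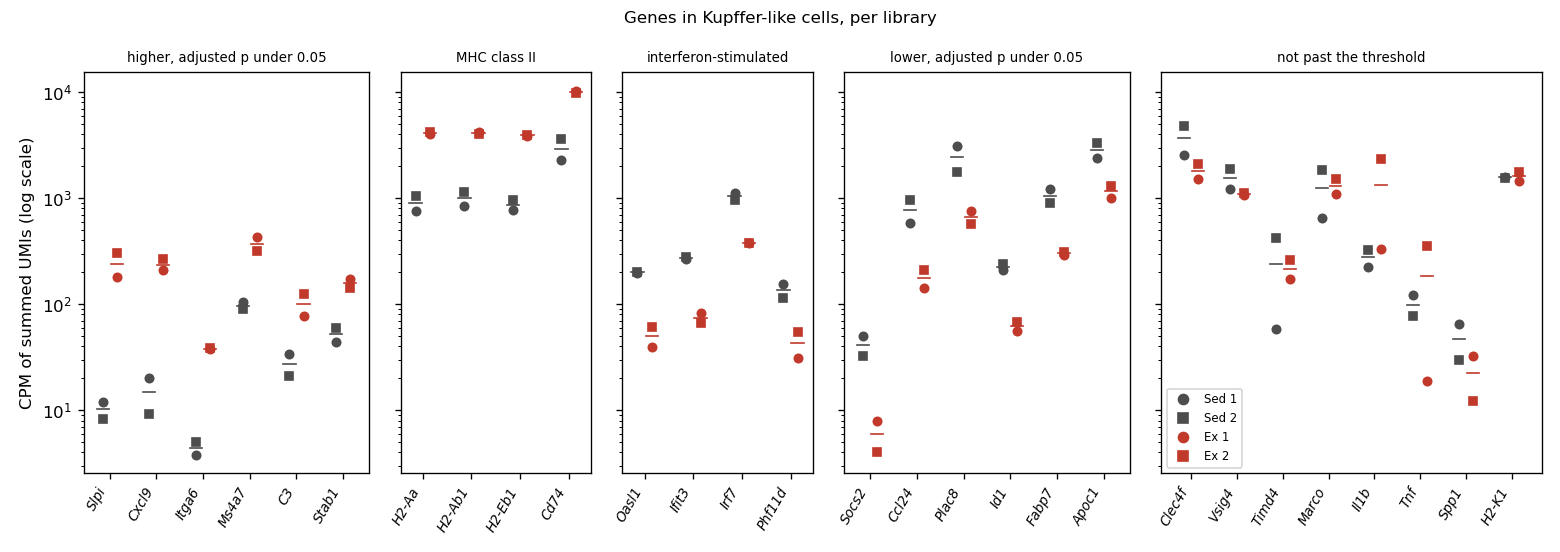
CPM of the summed UMIs of Kupffer-like cells on a log scale for genes named in the text, 1 symbol per library, with grey for sedentary, red for exercised, circles for replicate 1, squares for replicate 2 and short lines for the mean of each group. H2-Aa lay at 756 and 1043 CPM in the sedentary and at 4046 and 4233 CPM in the exercised libraries, while the symbols of Timd4, Marco and Tnf overlapped between the groups.

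The interferon-stimulated list moved down in Kupffer-like cells. Of its 37 members tested, 8 fell, 1 rose and 28 did not pass, and adjusted over the list alone 24 fell and 2 rose. The member that rose was Cxcl9, which interferon gamma induces. Besides Ifit3 and Irf7 (-1.46 ± 0.27, adjusted p = 0.0211), Phf11d fell, at -1.74 ± 0.32. The median change of the list was -0.84 (camera, adjusted p = 2.17e-09), with p = 0.0333 and adjusted p = 0.973 with an estimated correlation. Without Ex 1 or Ex 2 Irf7 had adjusted p = 0.139 or 0.191, and without Ex 1 Phf11d had 0.117. The MHC class II list moved up: 5 of 16 members rose and 11 did not pass, and adjusted over the list alone 7 rose and 1 fell. The members were H2-Aa at 2.20 ± 0.28, H2-Eb1 at 2.17 ± 0.27 (both adjusted p = 0.00323), H2-Ab1 at 2.04 ± 0.28, Cd74 at 1.77 ± 0.28 and H2-Ob, a modulator of peptide loading, at 2.61 ± 0.56, which stands outside the naming rule and was picked after its value was seen. The median was 0.69 (adjusted p = 0.000161), with adjusted p = 0.973 with an estimated correlation. Cd74 had adjusted p = 0.108 without Ex 1 and 0.138 without Ex 2.

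The monocyte-derived macrophage list was also called up, with a median of 0.91 (adjusted p = 0.00668, and 0.973 with an estimated correlation). Of its 15 members only Ms4a7, a membrane gene of macrophages, passed over all genes, at 1.96 ± 0.27 (adjusted p = 0.00519), and adjusted over the list alone 6 rose. Without Ex 1 the list had adjusted p = 0.322. Fn1, Ccr2 and Cd63 had 4.25 ± 0.63, 1.56 ± 0.34 and 0.93 ± 0.27 without passing over all genes. With 1 library left out the log2 change of Fn1 ran from 3.56 to 4.82 and that of Ccr2 from 1.19 to 2.23. Those fits have a single library in 1 group. The NF-kB and inflammatory cytokine list was called up at a median of 1.11 (adjusted p = 0.0469, and 0.989 with an estimated correlation), yet its only called member of 26, Il18, fell at -1.32 ± 0.26 (adjusted p = 0.0303). Adjusted over that list alone 3 rose and 2 fell. Il18 had adjusted p = 0.141 without Ex 1 and 0.0804 without Ex 2. Without Ex 2 the median of that list was -0.34 with adjusted p = 0.157, and without Sed 1 or Sed 2 the adjusted p was 0.162 or 0.0621. With doublets kept it was 0.0599 and at resolution 0.5 0.0575, and that list passed in 6 of 17 alternatives. Oxidative phosphorylation (88 tested, median -0.22, adjusted p = 0.00577) and ribosomal proteins (90 tested, median -0.28, adjusted p = 0.00285) were called down, with 0 members called by edgeR in each, also adjusted over the list alone, and both had adjusted p = 0.989 with an estimated correlation. Without Ex 2 the oxidative phosphorylation and ribosomal lists had adjusted p = 0.766 and 0.126, and without Sed 1 0.241 and 0.973, the ribosomal one then pointing up. With the stricter cell filter the ribosomal list had adjusted p = 0.188. Ndufs3 and Ndufb8, parts of complex I, had -0.73 ± 0.25 and -0.65 ± 0.25.

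Lists of RNA from other cells were called as well. The hepatocyte list was called up at a median of 1.38 (22 tested, adjusted p = 0.00154, and 0.989 with an estimated correlation), with Mup20 risen and Apoc1, an apolipoprotein gene that Kupffer cells also express, fallen at -1.30 ± 0.28. The T and B cell list was called up at a median of 1.47 (8 tested, adjusted p = 0.0105, and 0.973 with an estimated correlation), with 0 members past adjusted p over all genes and 3 adjusted over the list alone. In it Igkc had 33.7 ± 18.9 CPM in sedentary and 1731 ± 1192 CPM in exercised libraries. Its log2 change ran from 4.64 to 6.39 with 1 library left out, in fits with a single library in 1 group. The endothelial list was called up at a median of 0.86 (9 tested, adjusted p = 0.0102, and 0.973 with an estimated correlation), with Ptprb risen by 2.28 ± 0.44, a level that free RNA could give (adjusted p = 0.167 without Ex 1 and 0.0761 without Ex 2), and 4 members risen adjusted over the list alone. Without Ex 2 the hepatocyte and endothelial lists had adjusted p = 0.157 and 0.149, without Sed 2 the hepatocyte list 0.232, and without Ex 1 the T and B cell list 0.244. With doublets kept the T and B cell list had 0.104. The hepatocyte list turned to a median of -0.70 without the cluster of few UMIs (adjusted p = 0.0365), where the endothelial list had 0.0984, and the endothelial list turned to -0.84 with the stricter filter (0.668). The share of free RNA, from B cell transcripts found in these cells, was 5.39%, 10.4%, 11.8% and 12.97% in Sed 1, Sed 2, Ex 1 and Ex 2. The erythroid list (7 tested, median -0.98, adjusted p = 0.222) was not called, with the haemoglobin gene Hba-a1 at 4380 and 313 CPM in the sedentary and 2015 and 4.04 CPM in the exercised libraries. Without Sed 2 it was called, with adjusted p = 0.000128, and without Ex 1 with 0.000841. Of the 105 called genes, 10 had levels that free RNA could give by the share of B cell RNA. With hepatocyte genes in the share, which then ran from 125% to 206% and so exceeded all the RNA of a cell, only 15 of the 105 were left to test.

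The other 23 lists were not called in these cells. The T and NK cell recruiting chemokines (10 tested, median 0.81, adjusted p = 0.642) held Cxcl9 risen and Il18 fallen. The myeloid recruiting chemokines (12 tested, median -0.04, adjusted p = 0.795) and the alternative activation list (17 tested, median -0.23, adjusted p = 0.341) both held Ccl24 fallen, and the latter Stab1, a scavenger receptor gene, risen by 1.59 ± 0.27. Stab1 was also the single riser among phagocytosis and efferocytosis receptors (27 tested, median -0.11, adjusted p = 0.97). In the complement list (16 tested, median -0.14, adjusted p = 0.795) C3, the central complement component, rose by 1.90 ± 0.33, and in the lipid handling list (25 tested, median -0.07, adjusted p = 0.896) Apoc1 was the only called member. The antioxidant list (22 tested, median 0.06, adjusted p = 0.797) held Cat, the catalase gene, risen by 1.14 ± 0.25. In the naive and memory T list (7 tested, median 1.30, adjusted p = 0.0512) Satb1, Foxp1 and Igfbp4 rose, and free RNA could give the levels of Satb1 and Foxp1. Without Ex 2 Satb1, Foxp1 and Igfbp4 had adjusted p = 0.116, 0.0783 and 0.198, and without Ex 1 Foxp1 and Igfbp4 had 0.142 and 0.0708. Without Ex 2 C3 had adjusted p = 0.0781, Apoc1 0.288 and Cat 0.138, without Ex 1 Apoc1 and Cat had 0.326 and 0.126, and without Sed 1 Cat had 0.132.

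No member was called in the lists of Kupffer identity (16 tested, median -0.14, adjusted p = 0.583), the endothelial-like Kupffer subset (median 0.10, adjusted p = 0.795), MHC class I presentation (median -0.13, adjusted p = 0.795), fatty acid oxidation (median 0.05, adjusted p = 0.896), glycolysis (median 0.09, adjusted p = 0.412) and the tricarboxylic acid cycle (median -0.21, adjusted p = 0.244). The same held for lysosome and autophagy (median -0.02, adjusted p = 0.896), checkpoint ligands and receptors (median 0.16, adjusted p = 0.805), cytotoxic effectors (median 0.85, adjusted p = 0.795), T cell exhaustion (median 0.91, adjusted p = 0.0639), cell cycle (median -0.27, adjusted p = 0.0512) and neutrophil granules (median -0.31, adjusted p = 0.84). It held as well for hypoxia (median 0.27, adjusted p = 0.896), dissociation stress (median 0.02, adjusted p = 0.795; without Ex 1 up with 1.06e-06, without Ex 2 down with 1.4e-05) and the unfolded protein response (median -0.07, adjusted p = 0.97). Without Sed 2 the cell cycle, exhaustion and neutrophil granule lists were called, with adjusted p = 1.42e-08, 0.0319 and 0.00199. Without Ex 1 the cell cycle, exhaustion and naive and memory T lists had 0.000609, 0.00259 and 0.0225. Without Sed 1 the Kupffer identity, exhaustion and naive and memory T lists had 0.000464, 0.0465 and 0.0437, and without Ex 2 the last of these 0.000464. With the stricter cell filter the Kupffer identity list was called down, with 0.0224. The cell cycle list passed in 6 of 16 alternatives. In 8 of the 33 lists the median, the mean and the direction of the test differed in sign: myeloid recruiting chemokines, complement, cytotoxic effectors, hypoxia, lipid handling, fatty acid oxidation, the unfolded protein response and phagocytosis receptors, none of them called. In all, 9 of 33 lists were called by camera with its preset correlation, 6 up and 3 down. With an estimated correlation 0 were called and 1 had an unadjusted p under 0.05, and with fry 0 were called and 4 had one.

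The second comparison was the distribution of immune cells. Macrophages other than Kupffer cells made up 3.39% ± 0.237 of named immune cells in sedentary and 11.7% ± 3.66 in exercised mice, CD4 T-like cells 0.765% ± 0.0452 and 3.41% ± 0.182, NKT-like cells 0.818% ± 0.301 and 3.50% ± 0.755, and plasmacytoid dendritic-like cells 0.495% ± 0.294 and 1.95% ± 0.166. These 4 classes had unadjusted p between 0.00811 and 0.0298 in edgeR and did not pass the adjustment (adjusted p between 0.125 and 0.134). Their log2 changes were 1.79 ± 0.53, 2.15 ± 0.50, 2.09 ± 0.57 and 1.97 ± 0.65 in that order. The CD4 T-like class was a single cluster led by Foxp3, Tnfrsf4 and Ctla4, which are in the marker list of regulatory T cells. The class of other macrophages, also named from markers alone, was a single cluster too. Its score of 3.59 lay close to its classical monocyte score of 3.03. Neutrophil-like cells had 27.5% ± 11.6 and 11.04% ± 0.329 (adjusted p = 0.235), classical monocyte-like cells 21.5% ± 2.06 and 10.4% ± 0.753 (adjusted p = 0.235), and NK-like cells 1.86% ± 0.818 and 4.24% ± 0.387 (adjusted p = 0.235). Kupffer-like cells took 6.57% and 20.7% of the sedentary and 12.0% and 4.63% of the exercised libraries (adjusted p = 0.697), B-like cells 16.9% ± 6.49 and 29.0% ± 12.0 (adjusted p = 0.482) and CD8 T-like cells 6.71% ± 2.31 and 8.40% ± 1.93 (adjusted p = 0.745).

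The remaining classes were ILC1-like (1.92% ± 1.36 and 1.91% ± 0.335), cDC1-like (1.13% ± 0.442 and 1.01% ± 0.091), cDC2-like (1.11% ± 1.30 and 1.85% ± 0.436), proliferating lymphoid (1.21% ± 0.0279 and 1.21% ± 0.423), gamma-delta or type 17 T-like (0.408% ± 0.307 and 0.777% ± 0.207), migratory dendritic-like (0.400% ± 0.340 and 0.580% ± 0.152), mast or basophil-like (0.0706% ± 0.0548 and 0.408% ± 0.493) and plasma-like cells (0.266% ± 0.353 and 0.278% ± 0.142), with adjusted p between 0.319 and 0.99. So 0 of 18 classes passed in edgeR, and the exact permutation test on 2 against 2 libraries cannot give a two-sided p under 0.333. In simulated libraries a 4-fold fall of 1 class, drawn at random, was called in 8 of 100 runs and a 16-fold fall in 62 of 100. Rises were not simulated, so these runs do not give the rate for classes whose mean share rose. The bead enrichment for CD45 can set these shares. Endothelial-like cells, which lack CD45, took 1.42% and 3.95% of the kept cells in sedentary and 5.76% and 15.5% in exercised libraries. Without Sed 2, 9 classes were called, among them CD4 T-like (adjusted p = 0.0158), NKT-like (0.0114), plasmacytoid dendritic-like (0.0114), other macrophages (0.0345) and neutrophil-like cells (0.0232). At resolution 2 CD4 T-like (0.0442), NKT-like, regulatory T-like, plasmacytoid dendritic-like cells and other macrophages (0.0471 each) were called as higher, and at resolution 0.5 CD8 T-like cells as lower (-4.70, adjusted p = 0.0282).

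**Figure D2:**
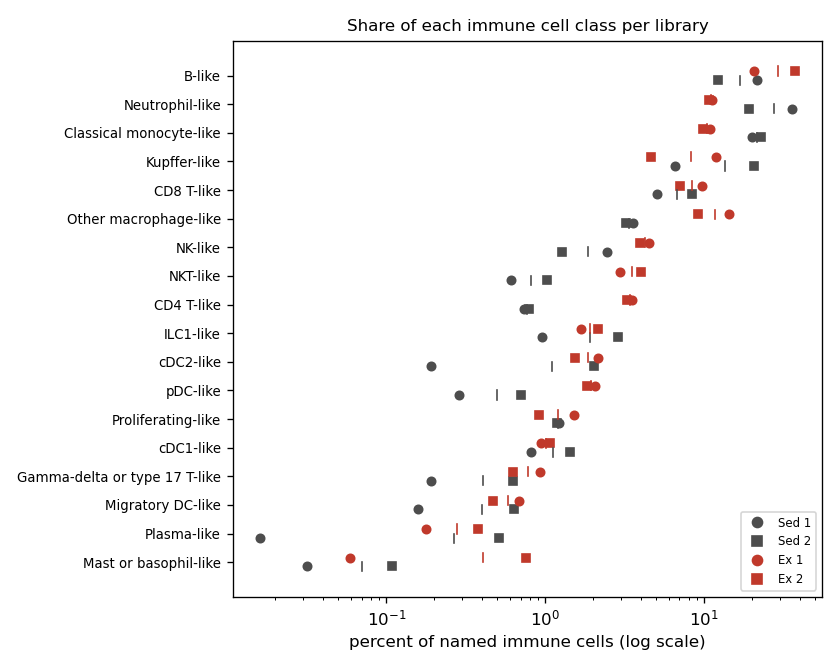
Percent of named immune cells in each of the 18 classes on a log scale, 1 symbol per library, with grey for sedentary, red for exercised, circles for replicate 1, squares for replicate 2 and a short line for each group mean. The macrophages other than Kupffer cells lay at 3.55% and 3.22% in the sedentary and at 14.3% and 9.11% in the exercised libraries, and the symbols of the Kupffer-like and B-like classes overlapped.

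The third comparison took the other immune classes, asking for their functional heterogeneity. Over the 10 classes with at least 30 cells in every library, 1872 calls were made, 918 up and 954 down, a sum that was 3080 without Sed 1, 6378 without Sed 2, 1937 without Ex 1 and 1295 without Ex 2. CD8 T-like cells held most of them, with 504 genes up and 548 down of 8604 tested (DESeq2: 447, of which 433 were shared), and 605 in all without Sed 2. Gzma, a granule protease of killer cells, fell from 8646 ± 910 to 129 ± 9.05 CPM (-6.07 ± 0.25, adjusted p = 5.36e-20), Gzmb by -3.40 ± 0.29, the pore-forming Prf1 by -2.16 ± 0.23, Ifng by -1.63 ± 0.23 and the inhibitory receptor gene Pdcd1 by -3.41 ± 0.27 (adjusted p = 1.7e-11). Of 22 cytotoxic effector genes 15 fell and 1 rose (16 and 1 adjusted over the list alone; median -1.57, adjusted p = 5.1e-10), and of 19 exhaustion genes 15 fell and 1 rose (16 and 1 adjusted over the list alone; median -1.64, adjusted p = 1.12e-12). Of 15 naive and memory T genes 9 rose and 0 fell (10 adjusted over the list alone; median 1.95, adjusted p = 7.7e-10). With an estimated correlation the p of these lists were 0.0208, 0.0144 and 0.143, with adjusted p = 0.333, 0.333 and 0.609. Fry called cytotoxic effectors and exhaustion (adjusted p = 0.036 each).

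Different clusters held most of this class in the groups. In sedentary mice 76.3% of the CD8 T-like cells lay in a cluster led by Gzmk, Ccl5, Tox, Gzma and Pdcd1, which held 1.8% of those of exercised mice. In exercised mice 63.8% lay in a cluster led by Gzmm, Sidt1 and Tcf7 and 24.6% in a cluster led by interferon-induced genes such as Ifit1 and Mx1. These 2 clusters had no CD8 marker among their 10 leading genes, and their CD8 T scores of 3.66 and 3.91 lay close to their NKT scores of 3.51 and 3.49. A further cluster, led by Dapl1, Lef1, Trnp1 and Tcf7, had CD8 T as its highest score (2.77) but was left without a name. It held 236, 37, 101 and 104 cells of Sed 1, Sed 2, Ex 1 and Ex 2. Those cells did not enter the tests of the naive, cytotoxic and exhaustion genes. The median mitochondrial share of CD8 T-like cells was 2.79% and 2.69% in sedentary and 4.50% and 4.90% in exercised libraries. The interferon-stimulated list was called up in this class (9 of 35 rose, 1 fell; 11 and 3 adjusted over the list alone; median 0.42, adjusted p = 0.00394, and 0.709 with an estimated correlation). The rule on size also named Fcrl6, at least 17.8-fold lower against a floor of 3 UMIs over the group, Dsc2, at least 14.8-fold lower, and Adgrg1, with a ratio of 0.0111 (0.00133 to 0.0409). Among rises it named Cd163l1, at least 18.1-fold higher, Kcnc1, with 1 UMI in sedentary libraries and a ratio of 43.7 (7.53 to 1756), and the noncoding Ifngas1, with a ratio of 43.7 (11.8 to 365). Cd163l1 did not pass with the stricter cell filter (edgeR adjusted p = 0.0879). With coarser clusters these cells did not form 1 class and were not tested.

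Macrophages other than Kupffer cells gave 85 genes up and 132 down of 8981 (DESeq2: 198), and 374 in all without Sed 1 and 1263 without Sed 2. In the lipid handling list, the profile of lipid-associated macrophages, 12 of 25 members fell and none rose (17 adjusted over the list alone; median -1.12, adjusted p = 1.7e-12), with p = 0.0211 and adjusted p = 0.421 with an estimated correlation and adjusted p = 0.0349 with fry. The falls named by size were those of Cxcl3 (70.8 ± 0.548 to 0.889 ± 1 CPM, -6.70 ± 0.46, adjusted p = 0.000149), Pdpn (-4.70 ± 0.55) and the lysosomal proton pump gene Atp6v0d2, with a ratio of 0.00661 (0.000165 to 0.0381). Myeloid recruiting chemokines were called down (3 of 13 fell, 9 adjusted over the list alone; median -1.30, adjusted p = 5.75e-09, and 0.421 with an estimated correlation). The MHC class II list (1 of 16 rose, 1 fell; 3 and 3 adjusted over the list alone; median 1.29, adjusted p = 0.00197, and 0.504 with an estimated correlation) and the interferon-stimulated list (2 of 37 rose; 7 rose and 1 fell adjusted over the list alone; median 0.38, adjusted p = 0.00145, and 0.593 with an estimated correlation) were called up. The largest rises were Cnn3 at 2.94 ± 0.57 and the B cell genes Ms4a1 at 2.78 ± 0.63 and Cd79a at 2.67 ± 0.43. With doublets kept Ms4a1 rose by 1.72 without passing (edgeR adjusted p = 0.0682), and DESeq2 did not call it (0.121). With thinned sums Cnn3 had an edgeR adjusted p of 0.103. The T and B cell list was called up as well (median 1.30, adjusted p = 4.75e-06, and 0.421 with an estimated correlation).

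Classical monocyte-like cells gave 117 genes up and 71 down of 10244, and neutrophil-like cells 124 up and 75 down of 7371. DESeq2 had more falls than rises in both, with 148 up and 211 down in monocytes and 64 up and 97 down in neutrophils. So had edgeR without the low-count filter (462 and 646, and 236 and 253) and without Sed 1 (451 and 498, and 236 and 250), and in monocytes without Sed 2 (689 and 750). In monocytes Ciita, the master regulator of MHC class II, rose from 3.03 ± 2.35 to 35.9 ± 3.86 CPM (3.54 ± 0.50), with Prg4 at 5.18 ± 0.68 and Fam71a at 3.66 ± 0.31, while Oas1c, Slc52a3 and Oas1g fell, at -3.03 ± 0.58, -2.89 ± 0.42 and -2.88 ± 0.35. The interferon-stimulated list was called down (8 of 37 fell, 3 rose; 17 and 5 adjusted over the list alone; median -0.93, adjusted p = 2.11e-05, and 0.615 with an estimated correlation) and the MHC class II list up (3 of 16 rose; 5 rose and 2 fell adjusted over the list alone; median 1.30, adjusted p = 0.000196, and 0.517 with an estimated correlation). In neutrophils Cxcl10 rose from 29.5 ± 15.5 to 290 ± 80.9 CPM (3.34 ± 0.40), with Mogat2 and Trim30c at 3.30 ± 0.54 and 3.27 ± 0.63. Ifi27l2a fell from 3551 ± 353 to 411 ± 1.51 CPM (-3.11 ± 0.27, adjusted p = 0.000289) and Stfa1 at -3.51 ± 0.52, and Oas1g had a ratio of 0.0809 (0.0164 to 0.242). The interferon list was called down in neutrophils (12 of 32 fell, 4 rose; 19 and 4 adjusted over the list alone; median -0.69, adjusted p = 1.47e-06, and 0.98 with an estimated correlation). In sedentary mice 89.5% of the monocytes lay in a cluster led by Vcan and F13a1 and in exercised mice 87.3% in one led by Lyz2 and Gm9733, and a neutrophil cluster led by Stfa genes and Retnlg held 43.9% and 5.2%. Without Ex 1 both classes gave 0 calls, and without Ex 2 monocytes gave 0 and neutrophils 7. Without Sed 1 they gave 949 and 486, and without Sed 2 1439 and 859. Oas1g in neutrophils had adjusted p = 0.543 without Ex 1 and 0.117 without Ex 2.

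B-like cells gave 64 genes up and 85 down of 9060 (DESeq2: 113), and 660 in all without Sed 2, 259 without Ex 1 and 71 with the stricter cell filter. The interferon-stimulated list was called down (8 of 33 fell, 1 rose; 13 and 1 adjusted over the list alone; median -1.24, adjusted p = 1.75e-10, and 0.805 with an estimated correlation), with Rtp4 at -2.84 ± 0.27 (adjusted p = 2.69e-05). Cxcl9 had 1 UMI in the sedentary and 85 in the exercised libraries, a ratio of 61.4 (10.7 to 2453). Ahnak and Hepacam2 rose by 1.85 ± 0.26 and 1.82 ± 0.45, the latter by only 0.97 without Sed 1. With the stricter cell filter neither passed (edgeR adjusted p = 0.501 and 0.178), and with thinned sums Hepacam2 had 0.12. The neutrophil gene Retnlg fell at -3.81 ± 0.42, and at -3.50 with doublets kept without passing (edgeR adjusted p = 0.156). The Kupffer gene Fabp7 fell at -3.07 ± 0.64, at -2.39 without Sed 2 and at -2.62 without Ex 2. Of the 149 edgeR calls in B-like cells DESeq2 shared only 45. It gave no adjusted p for Cxcl9, Ahnak, Hepacam2, Retnlg, Fabp7 and Rtp4. Over all kept cells Retnlg stood at 4870 CPM in sedentary and 628 CPM in exercised libraries. ILC1-like cells, the tissue-resident relatives of NK cells, gave 3 genes up and 13 down. The rises were the granzyme gene Gzmc (3.07 ± 0.31), the homing receptor gene Cxcr6 (1.64 ± 0.30) and S100a4 (1.35 ± 0.27). The falls included Ifi213 (-2.83 ± 0.52), S100a8 (-2.80 ± 0.57) and Ifit1, with a ratio of 0.0664 (0.00779 to 0.255). At resolution 0.5 Gzmc rose by 1.81 without passing (edgeR adjusted p = 0.310), and Ifit1 had 0.273. With thinned sums S100a8 had 0.226, and with the stricter cell filter Ifit1 had 0.0567. DESeq2 did not call Cxcr6 (0.485), S100a4 (0.0764), Ifi213 (0.494), S100a8 (0.9998) or Ifit1 (0.667). Without Ex 1, Ex 2 and Sed 2 that class gave 60, 30 and 65 calls. Of 19 interferon-stimulated genes 7 fell there (12 adjusted over the list alone; median -1.29, adjusted p = 7.2e-15, and 0.957 with an estimated correlation).

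NK-like cells gave 7 genes up and 9 down of 6473, with Il18r1, the receptor chain for interleukin-18, at 1.72 ± 0.26 (adjusted p = 0.00425), Gramd3 at 3.11 ± 0.58 and Lars2 at 1.67 ± 0.24. Chil3 was at least 19.65-fold lower, and Retnlg and Cd63 had ratios of 0.0751 (0.0149 to 0.235) and 0.0956 (0.0188 to 0.305). A cluster of 25 cells from Sed 1 alone, led by Gzmc, Gzmd and Gzme, held 10.6% of the sedentary NK-like cells. Without Sed 1 Chil3, Retnlg and Cd63 were under the count filter, and without Ex 2 Cd63 had adjusted p = 0.128. Over all kept cells Chil3 stood at 4455 CPM in sedentary and 515 CPM in exercised libraries. The effector genes did not pass in NK-like cells: Gzma -0.87 ± 0.24 (adjusted p = 0.124), Gzmb -0.63 ± 0.27, Prf1 -0.45 ± 0.26 and Ifng -0.38 ± 0.27, and Pdcd1, under the count filter there, had 27 UMIs in sedentary and 1 in exercised libraries, a ratio of 0.039 (0.000952 to 0.236). NK-like cells gave 177 calls without Ex 1 and 725 without Sed 2. CD4 T-like cells, a single cluster led by Foxp3, Tnfrsf4 and Ctla4, gave 9 up and 7 down, and 125 calls without Sed 1, 138 without Sed 2 and 10 without Ex 1. Klrd1 rose by 2.07 ± 0.40, and Xcl1 and Dapl1 had 1 sedentary UMI each with ratios of 41.4 (7.33 to 1642) and 16.3 (2.84 to 653). Rtp4, Gzma and Il7r fell at -1.93 ± 0.31, -1.92 ± 0.26 and -1.66 ± 0.22. With the stricter cell filter Dapl1 had an edgeR adjusted p of 0.0909, and at resolution 0.5 Gzma had 0.625. DESeq2 did not call Klrd1 and Dapl1 (adjusted p = 0.9997 each), Xcl1 (0.436) or Rtp4 (0.388). NKT-like cells gave 0 up and 6 down by edgeR, with Ifit3 at -2.96 ± 0.50, Ifit1 at -2.72 ± 0.52 and Rtp4 at -2.36 ± 0.44, and 471 genes passed an unadjusted p of 0.05. DESeq2 called 34 genes in NKT-like cells, 3 of them up. It shared 2 of the 6 edgeR calls and gave no adjusted p for Ifit3, Ifit1 and Rtp4. Without Sed 1, Sed 2, Ex 1 and Ex 2 that class gave 63, 244, 15 and 17 calls. With the stricter cell filter it gave 0 by edgeR, with adjusted p = 0.0834, 0.286 and 0.0834 for Ifit3, Ifit1 and Rtp4. Without Ex 2 Ifit1 and Rtp4 had 0.1299 and 0.0959. The median mitochondrial share of these cells was 4.14%, 3.45%, 4.75% and 4.91% in Sed 1, Sed 2, Ex 1 and Ex 2. In cDC1-like cells 5 genes rose and 8 fell, with Gpr183 at 2.42 ± 0.35, Mgl2 at a ratio of 22.4 (7.21 to 112), Ifi44 and Bcl2a1a at -3.02 ± 0.32 and -2.75 ± 0.37, and Chil3 at least 16.7-fold lower. Without Sed 1, Sed 2, Ex 1 and Ex 2 the cDC1-like cells gave 93, 380, 85 and 30 calls. With doublets kept they gave 0 up by edgeR and 2 down, with adjusted p = 0.0801 for Gpr183, 0.0648 for Mgl2, 0.061 for Bcl2a1a and 0.216 for Chil3. Without Ex 2 Mgl2 had 0.244. At resolution 0.5 Bcl2a1a and Chil3 had 0.400 and 0.169, and at resolution 2 Chil3 had 0.819. A cluster led by Xcr1, Tlr3 and Clec9a held 71.3% of the cDC1-like cells in sedentary and 45.1% in exercised mice, and one led by Gcsam, Ifi205 and Rab7b 14.7% and 41.5%. The interferon list was called down in NKT-like (median -0.52, adjusted p = 0.000346, and 0.77 with an estimated correlation) and cDC1-like cells (median -0.56, adjusted p = 4.44e-06, and 0.832 with an estimated correlation), and not in CD4 T-like (median -0.19, adjusted p = 0.272) or NK-like cells (median 0.45, adjusted p = 0.171).

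**Figure D3:**
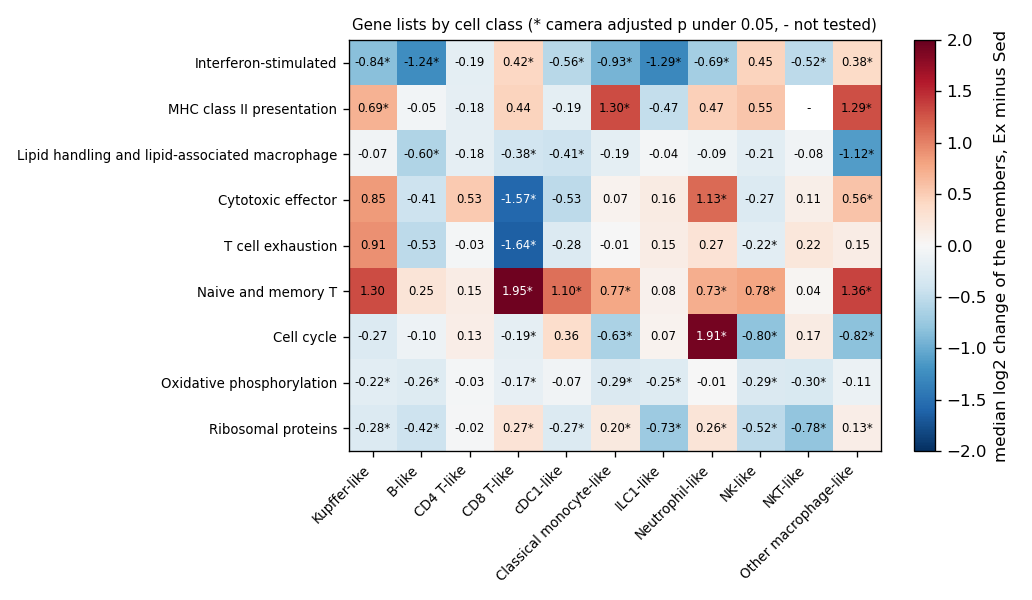
Median log2 change of the members of 9 gene lists, exercised minus sedentary, in Kupffer-like cells and the 10 other classes tested, with blue for lower, red for higher, a star for camera adjusted p under 0.05 at the preset correlation and a dash where the list was not tested. The interferon-stimulated list ran from -1.29 in ILC1-like to 0.45 in NK-like cells, and the lipid handling list was lowest, at -1.12, in macrophages other than Kupffer cells.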

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

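The test of the difference between Kupffer-like cells and other macrophages, the 2 free RNA tests on the MHC class II and neutrophil genes, the values for a mixture and for all RNA being free, and the reading of the mitochondrial test by the sign of the gap, were chosen after the results had been seen. Among genes named in Kupffer-like cells by size or picked in advance, a difference between 2 cell classes flagged the following. Values are the log2 change in Kupffer-like cells minus that in other macrophages, with the edgeR adjusted p. Genes named by size were chosen for large changes in Kupffer-like cells, so their direction here follows in part from that choice. Larger in Kupffer-like cells were Slpi at 6.07 (9.38e-05), Fcrls at 4.32 (0.00158), Itga6 at 3.80 (4.91e-05), Spp1 at 3.74 (0.0104), Pde3b at 2.66 (0.0058), Gpr132 at 2.39 (0.0209), Ahnak at 2.39 (0.000208) and Il21r at 2.39 (0.00756). Smaller were Trim30b at -2.01 (0.0077), Oasl1 at -1.75 (0.00436) and Ifit3 at -1.72 (0.00212). Spp1 fell in both classes, by -0.86 in Kupffer-like cells without passing and by -4.63 in other macrophages (0.0102), where Slpi fell too, by -1.44 (0.00979). The interferon-stimulated list differed by a median of -1.14 (camera, adjusted p = 4.81e-18, and 0.656 with an estimated correlation). It was not the only list called: lipid handling differed by 0.87 (camera, adjusted p = 3.19e-08) and hepatocyte RNA by 1.19 (3.71e-06). The MHC class II list did not pass, at -0.44 (camera, adjusted p = 0.162), with 0 genes called. Its rise was thus not shown to be particular to Kupffer-like cells. In all 234 of 9496 genes differed. A signal in cells outside the comparisons was the share of endothelial-like cells, 10.64% ± 6.90 in exercised and 2.68% ± 1.79 in sedentary libraries.

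The first pattern was the rise of MHC class II genes in Kupffer-like cells of exercised mice, where 5 of 16 members passed. By the share of B cell RNA, the rise of H2-Aa, H2-Ab1, H2-Eb1 and Cd74 was at least 10.53 times the level free RNA could give. This argues against that cause at this share only. In Ex 2 the share of B cell RNA ran from 0.41% in NKT-like to 28.2% in cDC1-like cells, so it was no fixed share of a library. The test therefore cannot exclude free RNA of another profile. That share was chosen after the version with hepatocyte RNA had been seen, whose shares of 125% to 206% exceed all the RNA of a cell. Had all RNA in these cells been free, with the profile of the kept cells, the rise would still have been at least 1.37 times that level. Cells of the 5 classes tested (other macrophages, B-like, cDC1-like, cDC2-like and classical monocyte-like cells), taken singly, did not account for the rise. The upper quartile of the share that other abundant genes implied was 0.403 of the share needed for cDC1-like cells and less for the others. These ratios add to 0.892, and those from the median implied share to 0.399, so a mixture stays open, as do migratory and plasmacytoid dendritic-like cells, which were not tested. A state of the Kupffer-like cells that moves with exercise stays open as a hypothesis, and exercise itself was not tested apart from the libraries.

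The second pattern was the fall of interferon-stimulated genes in Kupffer-like cells, where 8 of 37 members fell and 1 rose. The loss of the called members was, at the median, 10.47 times what free RNA could give by the same B cell share, which argues against that cause at this share. With the hepatocyte version none of these members, and none of the 4 genes of the first pattern, was left to test. Had all RNA been free, the loss would have exceeded the level for 4 of the 8, with a median ratio of 1.09. For mitochondrial RNA, the gap between the groups went from 0.287 to -0.161 percentage points with the stricter filter, so both exercised libraries then lay below both sedentary ones. The median of the list kept 0.985 of its size (-0.84 and -0.82, camera adjusted p = 8.14e-09), which argues against a higher mitochondrial share as the whole cause. With the main filter and an estimated correlation the list had adjusted p = 0.973. The prediction written in advance asked for a gap under 0.5 of its size and had not foreseen a change of sign.

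The third pattern was lower neutrophil genes in lymphoid classes, where 6 of 15 pairs of gene and class passed as falls and 0 as rises by edgeR, and Mmp9 pointed up in ILC1-like cells (1.79). Over the 15 pairs the change was lower than that over all cells by a median of -0.788 with SD 1.14, so free RNA cannot be told apart from another cause, the median being neither near 0 nor beyond its spread. Doublets cannot be told apart either: the 2% of B-like cells with most S100a8, S100a9 and Retnlg UMIs held 12.8% of 995 in Sed 1 and 43.89% of 303 in Sed 2, and the higher was taken after both had been seen. In Sed 1 49.1% of the cells held such a UMI, against 52.25% if spread evenly, and in Sed 2 22.4% against 32.0%. Sed 1 thus goes against doublets as the whole cause, and Sed 2 and the classes that were not searched keep it open. No biological explanation was tested.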

How the results depend on the processing

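The 105 changed genes of Kupffer-like cells were 359 without the low-count filter, 57 with doublets kept, 58 at resolution 0.5, 30 with sums thinned to the smallest total, where fewer genes were tested, and 61 to 420 with 1 library left out. With hepatocyte genes in the share of free RNA the count was 0 by edgeR with 374 genes left, among them 15 of the 105, all with the same direction. The shares of 125% to 206% in that version exceed all the RNA of a cell. What it left therefore cannot tell how far the calls depend on hepatocyte RNA. The sum of 1872 over the other classes was 4535 without the low-count filter and 1295 to 6378 with 1 library left out. Changed shares numbered 0, and 5 at resolution 2, 1 at resolution 0.5 and 0 to 9 with 1 library left out, 9 without Sed 2. Of the 9 changed lists, 1 was left with the hepatocyte version, 0 with an estimated correlation and 0 with fry, and 6 to 12 with 1 library left out. Why these counts moved was not tested.

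Results that reversed were the NF-kB list, with a median of -0.34 without Ex 2 (1.93 without Ex 1) and, with the hepatocyte version, a test that pointed down without a call at a median of 0.61 (adjusted p = 0.592), the dissociation list at -0.70 without Ex 2 (0.74 without Sed 2), the ribosomal list at -0.0199 without Sed 1, tested upward (-0.53 without Sed 2), the hepatocyte list at -0.70 without the cluster of few UMIs and the endothelial list at -0.84 with the stricter filter. Timd4 reversed to 1.87 without Sed 2 (-0.999 without Sed 1) and Tnf to -2.38 without Ex 2 (1.83 without Ex 1), and the cause was not tested in these. The share of CD8 T-like cells reversed to -4.70 at resolution 0.5, where a cluster of 788 cells, 476 and 217 of them from Ex 1 and Ex 2, was left without a name.

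With the replicate block 426 genes changed in Kupffer-like cells, 3563 over the other classes, 0 shares and 11 lists, while other macrophages gave 41 and CD4 T-like cells 6. Libraries of the same number resembled each other little, with r = 0.173 in Kupffer-like cells, 0.164 in NK-like cells, 0.103 in cDC1-like cells and -0.0274 to 0.0922 in the others. Of 536 values for 33 Kupffer lists 469 stayed on their side of the threshold, 39 were weaker, 22 stronger and 6 reversed. For 2256 values of 154 named Kupffer genes these counts were 1981, 121, 152 and 2. Of 877 for genes of other classes 762 stayed on their side, 108 were weaker and 7 stronger. Of 213 for shares 199 stayed, 13 were stronger and 1 reversed. A change of sign counted as reversed only where the main or the alternative fit passed. The share of Kupffer-like cells thus counted as staying, though its log2 change went from -0.72 to 0.34 without Sed 2. At the depth and the number of libraries here, the gene test called 24% of 2-fold and 93% of 4-fold changes in simulated sums, and which of them sets this limit was not tested. Spread particular to single genes was not simulated, nor were changes in genes of low level, so these rates do not cover either.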

Other observations

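In CD4 T-like cells of exercised mice the glycolysis list was higher (2 of 18 members rose, 12 adjusted over the list alone; median 0.87, camera adjusted p = 2.71e-07, and 0.802 with an estimated correlation). In neutrophil-like cells the cell cycle list was higher (19 of 39 rose, 36 adjusted over the list alone; median 1.91, adjusted p = 1.26e-23, and 0.98 with an estimated correlation). A cluster of that class led by Fcnb, Camp and Cebpe held 0.7% of it in sedentary and 3.1% in exercised mice, and the class gave 0 gene calls by edgeR without Ex 1 and 7 without Ex 2. In cDC1-like cells the unfolded protein response list was higher (0 of 14 rose by edgeR, 8 adjusted over the list alone; median 0.75, adjusted p = 4.89e-06, and 0.885 with an estimated correlation). The clusters of that class also shifted, one led by Gcsam, Ifi205 and Rab7b holding 14.7% of it in sedentary and 41.5% in exercised mice.

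Clusters without a name held 6.77%, 6.06%, 5.88% and 6.91% of the kept cells in Sed 1, Sed 2, Ex 1 and Ex 2.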
